A study of Drosophila melanogaster and Drosophila sechellia with 8 samples.

How the data were processed

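Whole bodies of pooled virgin flies, 3 days old, reared on corn medium per the labels' protocols, were compared between Drosophila melanogaster Canton-S and Drosophila sechellia on 8 Agilent 2-colour oligonucleotide arrays. Per the labels, 500 ng of total RNA was amplified and labelled with Cy3 or Cy5, 825 ng of labelled cRNA of each species was hybridised, and each biological replicate of each sex was hybridised on 2 arrays with the dyes exchanged. Images were quantified with Agilent Feature Extraction 10.2, per the submitters' processing notes. The deposited scanner tables gave, per the file headers, each spot's intensity on a linear scale as the mean signal and the local background median in both channels, together with the software's processed signal, its log10 ratio of red over green and its marks for outlier, saturated and well above background spots. The deposited series matrix held log10 ratios. Set against the scanner values, 7 of its 8 columns equalled the software's log10 ratio of red over green (r = 0.999999), not turned for dye exchanges and with medians of 0, 0.0118, 0, 0, 0, 0 and 0. The column of the dye-exchanged array of male replicate 2 equalled the error of that ratio instead (r = 0.999999, against -0.0742 with the ratio; median 0.0801) and was left out of the alternative that uses the matrix. The genome build behind the probe positions is not given in the sources used here, and no reference genome was used.

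Groups were taken from the labels: melanogaster and sechellia RNA of males and of females, in 2 replicates per sex. The replicate numbers did not pair males with females. The dye labels of the replicates opposed each other, and every array was turned by the labels of replicate 2, as a choice made after the values were seen. The other reading turns every sign.

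Spots were read with limma 3.58.1 in R 4.3.3 and handled with the package data.table, version 1.17.8. Background was corrected by normexp with an offset of 50 on mean signals and local background medians, and log ratios were normalised within each array by loess, with control spots at weight 0. Control spots (1417 per array) and spots marked as outliers (84 to 159 per array) were left out. Saturated spots were not left out, and 0 were found. Spots of one probe were averaged, giving 32162 distinct probes, of which 31585 had a position and 470 carried several CG numbers. A probe was tested if it was well above background on at least 3 of 4 arrays in at least 1 of the 4 groups of species and sex, which kept 25532 probes. The arrays of one replicate were averaged after turning, and a gene's value was the mean of its tested probes. Of 24347 genes and transcripts on the array, 14185 had a CG number. 18922 had a tested probe, 18910 were tested and 12 were left out for outlier spots, Acp70A among them. Names are those of the array's design and can be old. In 4845 genes with several probes, probes disagreed in 292 (6.03%) in males and 218 (4.50%) in females.

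One linear model per gene was fitted over the 4 replicates, with a mean for each sex and moderated standard errors (residual degrees of freedom 2, prior 2.43). It gave the species difference in males, in females and averaged, and the male minus female difference. Values are log2 ratios of sechellia over melanogaster, and p-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. All adjusted p-values of genes are limma's and all tests were two-sided. The test was chosen for log ratios of 2-colour arrays. Where a gene was not well above background in one species, the difference is given as a bound: the brighter species' mean against, per array, the higher of the lowest signal among probes well above background and the gene's own signal, from channel levels after loess and Aquantile. Levels per species came from the channel levels, averaged over the 2 arrays of a replicate. The sex difference within each species came from a fit on these levels, with the replicate that joins both species as block (correlation 0.270). Leaving out a replicate used the block correlation of all data, and assumes that a lone replicate varies like the others.

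There were 28 gene lists. No ionotropic receptor was found on the array by name, and the remaining 27 lists were tested in males, in females and for the difference with camera at a preset correlation of 0.01, adjusted over all 81 tests. The tests of camera with an estimated correlation and of fry were alternatives. None of the 29 calls of camera held with an estimated correlation. Groups, tests, lists, most alternatives and the rule for named genes were chosen before the data were examined. Alternatives on the dye labels, on the direction of calls and on the overlap, the leave-outs of lists, of the sex difference and of the sex-bias classes, and the lists with the scanner's processed signals were chosen after seeing the data. Named genes were, in each sex, among genes past the threshold and in the same direction on all 4 arrays, the 8 highest and 8 lowest well above background in both species and the 4 highest and 4 lowest not well above background in one. For the male minus female difference they were the 8 highest and 8 lowest past the threshold, of which there were none. Up to 4 members of each list with the smallest adjusted p, and the label checks Yp1, Yp2, Yp3, roX1, roX2, Acp70A, Acp26Aa and Sxl, were named as well. Which of the list members named by the rule are printed was chosen after their values were seen. Single genes of the sex difference were chosen in the same way.

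The alternatives covered background correction, the scanner's processed signals, median centring, the filter on dim probes, the treatment of several probes, the use of the dye exchanges, the samples in the fit, the series matrix, a separate-channel fit (intraspot correlation 0.860), the labels, and leaving out each replicate. The separate-channel fit held no term for the replicate, so it counted the 2 arrays of a replicate as independent. Depth on an array is signal over background: between 56.9% and 81.5% of spots were well above background in a channel. In a test on simulated data with the 18910 genes of the male comparison, 19.4% of 67 genes changed by 1 on the log2 scale were recovered, 94.0% of 67 changed by 2 and 100% of 66 changed by 4, with 10 of 18710 unchanged genes called. With 9455 genes changed by 2, 99.5% were recovered and 266 of 9455 unchanged genes were called. The list test called 0 of 81 tests of unmoved lists, by camera. Those lists were random and their genes varied independently, so this cannot show how the test behaves on lists of correlated genes. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.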

Results

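RNA from whole virgin adults of 2 fly species, 3 days old, was compared directly on 2-colour oligonucleotide arrays. The species were Drosophila melanogaster, of the wild-type laboratory strain Canton-S, and its relative Drosophila sechellia, known for living on the fruit of Morinda citrifolia. Each array held RNA of both species from one sex. There were 8 arrays, 4 for males and 4 for females, made from 2 biological replicates per sex, and each replicate was hybridised on 2 arrays with the dyes exchanged. The labels name pooled whole bodies, and nothing in them says whether the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision. Of 43603 non-control spots per array, between 56.9% and 81.5% were well above background in a channel, and 0 were saturated. After averaging probes, 18910 genes and transcripts were tested. The probes were designed on melanogaster, so sequence differences can lower the sechellia signal, and this was not tested for single genes or lists.

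The direction of the species difference was not settled by the labels. By the labels, the first array of replicate 1 carried melanogaster in Cy3 and the first array of replicate 2 carried sechellia in Cy3, in both sexes, yet the red over green log ratios of those 2 arrays correlated positively across genes (r = 0.883 in males and 0.923 in females). Of the 28 pairs of arrays, 16 had log ratios whose correlation opposed their labels, and these 16 were the pairs that join a replicate 1 array with a replicate 2 array. Within a replicate the exchanged dyes behaved as labelled (r = -0.964, -0.978, -0.941 and -0.969). With the labels of both replicates as written, limma called 0 genes in males and 0 in females at an adjusted p under 0.05, with 17 and 0 at an unadjusted p under 0.05. All values are therefore given with every array turned by the labels of replicate 2, a reading chosen after the values were seen. Under the labels of replicate 1, the species names change places in every sentence and every sign turns. In the reading used, the lowest correlation between any pair of arrays was 0.630, and within a sex 0.820.

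Known sex-limited transcripts were measured in every sample, as a check of the labels. The dosage compensation RNA roX1 had mean log2 levels of 12.6 ± 0.71 and 12.2 ± 0.26 (SD, n = 2) in melanogaster and sechellia males, against 6.67 ± 0.01 and 7.38 ± 0.59 in females. The seminal fluid gene Acp26Aa had levels of 15.2 ± 0.58 and 15.9 ± 0.17 in males and was not well above background on any female array. roX2 was well above background on all male arrays (9.08 ± 0.41 and 7.37 ± 0.12) and on 0 of 4 female arrays of either species. Sex peptide (Acp70A), which was not tested because of an outlier spot, had levels of 13.3 ± 0.09 and 13.3 ± 0.20 in males and 6.30 ± 0.02 and 6.31 ± 0.05 in females. Sxl, the switch gene of female development, was at 8.62 ± 0.28 and 8.87 ± 0.13 in males and 10.3 ± 0.23 and 10.1 ± 0.15 in females. Yolk protein genes stood higher in male replicate 1 than in male replicate 2, in the samples of both species. Yp1 stood at 17.7 in melanogaster male replicate 1 and at 6.16 in male replicate 2, while melanogaster females had 16.5 and 16.2. In sechellia, Yp1 stood at 11.1 and 7.05 in male replicates 1 and 2 and at 17.0 and 17.1 in females. Yp2 (16.1 and 6.47) and Yp3 (17.4 and 7.89) showed the same gap between the 2 melanogaster male replicates. In sechellia, Yp2 stood at 12.9 and 6.76 in male replicates 1 and 2 and at 15.7 and 15.8 in females. Yp3 stood at 12.3 and 6.21 in sechellia males, with 12.8 and 12.7 in sechellia females, and the eggshell gene Vm26Aa at 13.9 and 6.35, with 17.2 and 17.1 in females. Of 52 yolk, eggshell and female germline genes at least 16-fold higher in melanogaster females than in melanogaster male replicate 2, 52 were at least 2-fold higher in melanogaster male replicate 1 than in male replicate 2. Under the labels of replicate 1, the species names of the 2 samples change places.

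**Figure D1:**
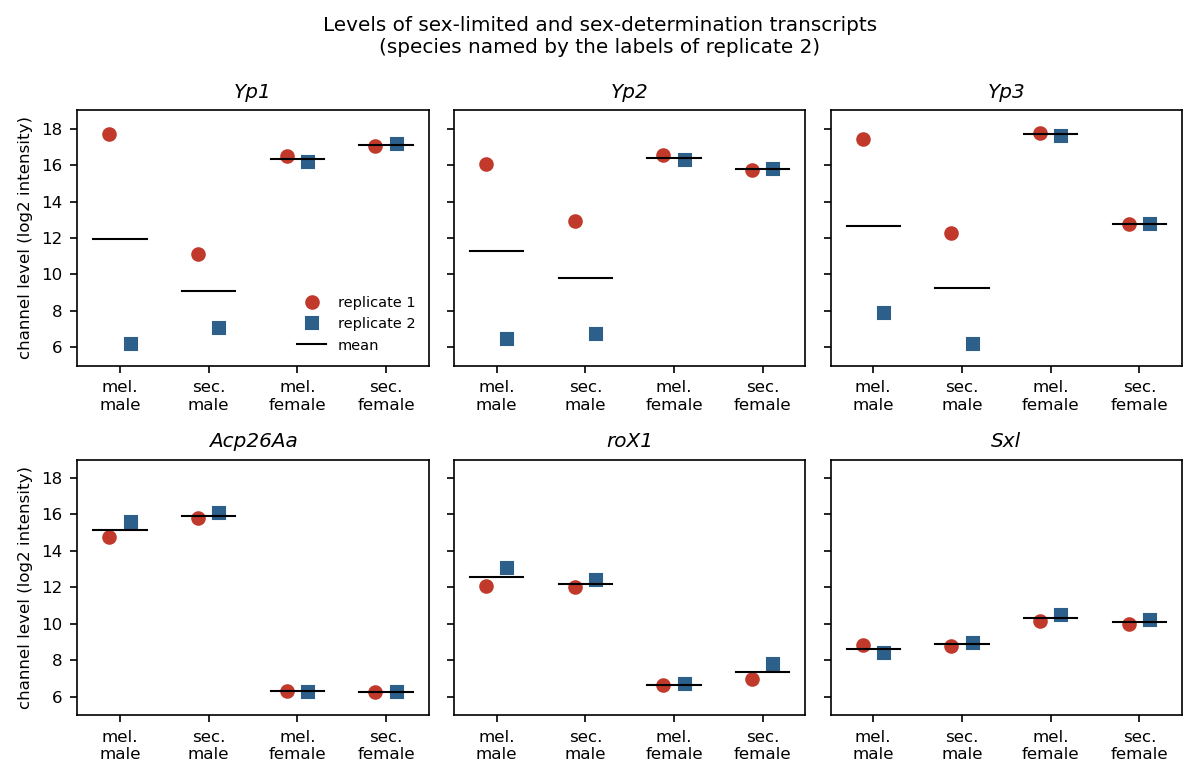
Log2 levels of sex-limited transcripts in each RNA sample, by species, sex and replicate, with 1 point per replicate. Yp1 stood at 17.7 in male replicate 1 and 6.16 in male replicate 2 of the species named melanogaster by the labels of replicate 2 (sechellia with the sign turned), while roX1 had means of 12.6 and 12.2 in males and 6.67 and 7.38 in females.

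In males, the accessory gland, testis and digestive lists were called lower in sechellia, and the phototransduction and cuticle lists higher. Among 44 measured accessory gland and seminal fluid genes, 27 fell and 8 rose, with 9 not past the threshold, 36 past it when adjusted over the list alone, and a median log2 difference of -1.98. The list was past the threshold by camera (adjusted p = 0.00176), with adjusted p = 0.970 with an estimated correlation. Acp62F, a protease inhibitor of the seminal fluid, was 31.7-fold lower (log2 -4.99 ± 0.34, SE, n = 2 replicates), CG31872 was 20.1-fold lower (log2 -4.33 ± 0.22) and Acp98AB 18.3-fold lower (log2 -4.19 ± 0.23). Of 45 testis and sperm genes, 21 fell and 2 rose, 22 were not past the threshold and 25 were past it when adjusted over the list alone, with camera's adjusted p = 0.00118 and adjusted p = 0.970 with an estimated correlation. The list's medians were -0.54 and -1.36 in male replicates 1 and 2. In melanogaster, 1307 genes were at least 16-fold higher in male replicate 2 than in females, and the median log2 of male replicate 1 over replicate 2 in these was -0.68. Choosing these genes as high in male replicate 2 can favour such a negative median. Mst87F, a sperm tail protein, was 30.8-fold lower (log2 -4.94 ± 0.40) and mip40, a subunit of a chromatin complex, 14.9-fold lower (log2 -3.90 ± 0.28). Mst57Da (log2 -2.53 ± 0.19) and Mst57Db (log2 -4.15 ± 0.33) stand on this list by name and are known from the accessory gland. With only probes well above background in both species and both sexes, a filter that leaves out genes silent in females, the adjusted p was 0.614 for the accessory gland list and 0.0520 for the testis list.

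Lists of digestive and detoxification genes held more genes that fell than rose in sechellia males. Of 38 digestive proteases, amylases and maltases, 24 fell, 2 rose and 12 were not past the threshold, 27 were past it when adjusted over the list alone, and the median was -1.84 (-1.93 and -2.08 in the 2 replicates). Camera gave an adjusted p = 2.84e-05, and adjusted p = 0.970 with an estimated correlation. Jon65Aiv and Jon44E, serine proteases of the midgut, were 32.6-fold lower (log2 -5.03 ± 0.32) and 15.9-fold lower (log2 -3.99 ± 0.26). Of 14 UDP-glycosyltransferases, 7 fell and 0 rose, 7 were not past the threshold and 9 were past it when adjusted over the list alone (camera adjusted p = 0.00979, and adjusted p = 0.970 with an estimated correlation), led by Ugt36Bc (log2 -3.28 ± 0.32) and Ugt37b1 (log2 -2.49 ± 0.33). Of 83 cytochrome P450 genes, 39 fell, 14 rose and 30 were not past the threshold, with 57 past it when adjusted over the list alone (camera adjusted p = 0.0308, and adjusted p = 0.970 with an estimated correlation). Cyp6w1 was 49.7-fold lower (log2 -5.63 ± 0.33) and Cyp6a18 was 7.20-fold higher (log2 2.85 ± 0.15). Of 21 glutathione S-transferases, 8 fell and 2 rose, 11 were not past the threshold, 11 were past it when adjusted over the list alone, and the list itself was not past it (adjusted p = 0.0561). GstE9 was 72.1-fold lower (log2 -6.17 ± 0.56) and GstE10 4.58-fold lower (log2 -2.19 ± 0.22). Without male replicate 2 the P450 list was not past the threshold (adjusted p = 0.204), and with only probes well above background in both species and both sexes it had an adjusted p of 0.117.

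The phototransduction and cuticle lists held more genes that rose than fell in sechellia males. Of 27 phototransduction genes, 15 rose, 3 fell and 9 were not past the threshold, 19 were past it when adjusted over the list alone, and the median was 1.01. Camera gave an adjusted p = 0.000338, and adjusted p = 0.970 with an estimated correlation. The rhodopsins Rh5 and Rh6 were 11.8-fold higher (log2 3.56 ± 0.25) and 7.86-fold higher (log2 2.98 ± 0.23), and inaD, the scaffold of the signalling complex, was 6.54-fold higher (log2 2.71 ± 0.23), while the eye G protein subunit Gbeta76C was 5.06-fold lower (log2 -2.34 ± 0.16). Of 65 cuticle protein genes, 28 rose, 7 fell and 30 were not past the threshold, with 38 past it when adjusted over the list alone (camera adjusted p = 0.000878, and adjusted p = 0.970 with an estimated correlation). Cpr97Ea was 12.3-fold higher (log2 3.63 ± 0.29) and Cpr65Ax1 6.44-fold higher (log2 2.69 ± 0.18). Of 26 muscle genes, 5 rose, 6 fell and 15 were not past the threshold, with 13 past it when adjusted over the list alone (camera adjusted p = 0.442).

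Among chemosensory genes, the odorant receptor list was past the threshold in males. Of 33 measured odorant receptors, 5 rose and 1 fell, 27 were not past the threshold and 1 was past it when adjusted over the list alone, with a median of 0.30 (camera adjusted p = 0.0225, and adjusted p = 0.970 with an estimated correlation). The list was not past the threshold with median centring (adjusted p = 0.0569), with only probes well above background in both species and both sexes (0.170) or without male replicate 2 (0.0534). Or85f was at least 2.89-fold higher, with melanogaster not well above background, and its call was lost without male replicate 2 (adjusted p = 0.0513). Of 28 gustatory receptors, 6 rose, 2 fell and 20 were not past the threshold, with 7 past it when adjusted over the list alone (camera adjusted p = 0.120). Of 48 odorant-binding proteins, 21 fell, 7 rose and 20 were not past the threshold, with 29 past it when adjusted over the list alone (camera adjusted p = 0.0524). Obp56d was 15.1-fold lower (log2 -3.92 ± 0.16) and Obp50a 13.8-fold higher (log2 3.78 ± 0.15).

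Yolk, eggshell and female germline genes were compared in males with the sample difference of replicate 1 beside them. Of 37 yolk and eggshell genes, 3 fell (CG1077, fs(1)N and Yp3), 0 rose and 34 were not past the threshold, with 0 past it when adjusted over the list alone. CG1077 and fs(1)N lost their calls without male replicate 1 (adjusted p = 0.0535 and 0.0540), and Yp3 without female replicate 1 or 2 (adjusted p = 0.0716). Camera called the list lower (median -1.53, adjusted p = 0.0166), with adjusted p = 0.970 with an estimated correlation. The list's median was -3.42 in male replicate 1 and 0.05 in male replicate 2, and without male replicate 1 its direction turned (adjusted p = 0.356). The median level of the list was 13.1 and 6.38 in melanogaster male replicates 1 and 2 and 13.7 in melanogaster females, and 9.21 and 6.59 in sechellia male replicates 1 and 2 and 13.2 in sechellia females. Of 43 female germline genes, 9 fell, 3 rose and 31 were not past the threshold, with 12 past it when adjusted over the list alone (camera adjusted p = 0.329), and the list medians were -1.25 and 0.06 in the 2 replicates. The piRNA pathway genes mael (log2 -2.24 ± 0.19) and vas (log2 -2.69 ± 0.28) were among those that fell.

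Of the 18910 genes tested, 7691 (40.7%) differed between the species in males at an adjusted p under 0.05 by limma. Of these, 3118 were higher and 4573 lower in sechellia, or 59.5% lower, which becomes 40.5% with the sign turned. The share lower was 47.7% with the scanner's processed signals, 70.2% with median centring and 47.4% with only probes well above background in both species and both sexes. At least 2-fold differences numbered 5325, of which 1634 were higher and 3691 lower. Among genes well above background in both species, the 8 highest ran from CG17738 (41.0-fold, log2 5.36 ± 0.24, adjusted p = 0.00483) through v, Hex-t2, Su(P), Dbi, CG4683, CG33459 and CG13749 (18.5-fold, log2 4.21 ± 0.24). v (CG2155, probe at X 10819587 to 10819646 in the array's annotation, whose genome build is not given in the sources used here) encodes the tryptophan dioxygenase of brown eye pigment synthesis and was 39.2-fold higher (log2 5.29 ± 0.16). Dbi, an acyl-CoA binding protein, was 24.1-fold higher (log2 4.59 ± 0.18), and Hex-t2, a testis hexokinase, 26.2-fold higher (log2 4.71 ± 0.17). CG4683 was 23.1-fold higher, with 1 of its 4 arrays apart from the others (3.64, nearest 4.74). The 8 lowest ran from CG34335 (172-fold lower, log2 -7.43 ± 0.69, adjusted p = 0.00556) through RpL38, CG8708, CG2668, CG3164, Spn43Ab, GstE9 and CG1394 (69.8-fold lower, log2 -6.12 ± 0.49). RpL38 (CG18001, probe at 2R 403538 to 403597), a protein of the large ribosomal subunit, was 155-fold lower (log2 -7.27 ± 0.56). Whether a sequence difference from the melanogaster probe lowers this value was not tested. CG3164 (log2 -6.31 ± 0.84) lost its call without male replicate 2 (adjusted p = 0.0542). In sechellia males, 849 genes were not well above background while melanogaster was, and 124 the reverse. The largest bound among the genes well above background in melanogaster only was 9.76-fold. By log2 difference, the 4 highest named genes past the threshold were at least 4.28-fold (CG5770), 3.98-fold (CR9337), 3.74-fold (defl) and 3.47-fold (CG41250) higher. The 4 lowest were at least 5.68-fold (l(3)neo26), 4.45-fold (CG9091), 4.43-fold (Orc6) and 4.34-fold (MESK4) lower. Each of these 8 lost its call without 1 of the male replicates, with adjusted p up to 0.232 (CR9337 without male replicate 2). The count of called genes was 4966 without male replicate 1 and 3372 without male replicate 2, and 12947 with a separate-channel fit.

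In females, the phototransduction, muscle and cuticle lists were called higher in sechellia, and the glycosyltransferase and ribosomal protein lists lower. Of 27 phototransduction genes, 17 rose, 1 fell and 9 were not past the threshold, 20 were past it when adjusted over the list alone, and the median was 1.34 (0.99 and 1.73 in the 2 replicates). Camera gave an adjusted p = 8.36e-07, and adjusted p = 0.970 with an estimated correlation. Rh5 was 15.1-fold higher (log2 3.92 ± 0.25, SE, n = 2 replicates), Rh6 12.0-fold higher (log2 3.58 ± 0.23) and inaD 10.4-fold higher (log2 3.37 ± 0.23), with Gbeta76C again lower (log2 -2.12 ± 0.16). Of 26 muscle genes, 13 rose, 1 fell and 12 were not past the threshold, with 16 past it when adjusted over the list alone (camera adjusted p = 0.000310, and adjusted p = 0.970 with an estimated correlation). The flight muscle actin Act88F was 8.35-fold higher (log2 3.06 ± 0.32) and the troponin C genes TpnC73F and TpnC47D were 5.34-fold (log2 2.42 ± 0.19) and 4.81-fold higher (log2 2.27 ± 0.17). Of 65 cuticle protein genes, 24 rose, 5 fell and 36 were not past the threshold, with 29 past it when adjusted over the list alone (camera adjusted p = 0.000311, and adjusted p = 0.970 with an estimated correlation). Lcp65Ab1 was 9.52-fold higher (log2 3.25 ± 0.29) and Cpr65Ax1 7.12-fold higher (log2 2.83 ± 0.18).

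Of 14 UDP-glycosyltransferases, 9 fell and 0 rose in females, 5 were not past the threshold and 12 were past it when adjusted over the list alone, with a median of -1.07 (camera adjusted p = 0.000878, and adjusted p = 0.970 with an estimated correlation). Ugt36Bc fell (log2 -1.98 ± 0.32), as did Ugt (CG6850, log2 -2.02 ± 0.19), which stands on this list by its name alone. Both lost their calls without female replicate 2 (log2 -2.34 and -1.76), as did Ugt36Bc without female replicate 1 (log2 -1.62). Of 85 cytosolic ribosomal protein genes, 24 fell, 2 rose and 59 were not past the threshold, with 26 past it when adjusted over the list alone (camera adjusted p = 0.00448, and adjusted p = 0.970 with an estimated correlation). RpS6 was 21.3-fold lower (log2 -4.42 ± 0.24) and RpS14b 5.63-fold lower (log2 -2.49 ± 0.16), and the list was not past the threshold without female replicate 1 (adjusted p = 0.0671). In males, 21 of the 85 fell and 2 rose, 62 were not past the threshold and 16 were past it when adjusted over the list alone (camera adjusted p = 0.0524). Sequence differences from the melanogaster probes were not told apart from expression in this list.

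Of 29 cuticular hydrocarbon genes in females, 8 rose, 4 fell and 17 were not past the threshold, with 12 past it when adjusted over the list alone (camera adjusted p = 0.0441, and adjusted p = 0.970 with an estimated correlation). The fatty acyl desaturase desat2 (CG5925, probe at 3R 8263454 to 8263513) was 12.0-fold higher in females (log2 3.59 ± 0.19) and 16.4-fold higher in males (log2 4.04 ± 0.19). This list was not past the threshold with median centring (adjusted p = 0.817), with the scanner's processed signals (0.144), with only probes well above background in both species and both sexes (0.0965) or without male replicate 1 (0.0932), male replicate 2 (0.115) or female replicate 2 (0.132). In males 9 of the 29 fell, 3 rose and 17 were not past the threshold, with 12 past it when adjusted over the list alone (camera adjusted p = 0.604). Of 83 P450 genes in females, 25 fell, 18 rose and 40 were not past the threshold, with 55 past it when adjusted over the list alone (camera adjusted p = 0.442). Cyp6a18 was 27.2-fold higher (log2 4.77 ± 0.15) and Cyp12d1-d 23.5-fold higher (log2 4.55 ± 0.23), while Cyp6a22 was 8.58-fold lower (log2 -3.10 ± 0.17). Of 21 glutathione S-transferases, 6 fell and 4 rose, 11 were not past the threshold and 13 were past it when adjusted over the list alone (camera adjusted p = 0.837). Of 38 digestive genes, 14 fell, 11 rose and 13 were not past the threshold, with 31 past it when adjusted over the list alone (camera adjusted p = 0.604). Jon99Ci was 25.1-fold lower (log2 -4.65 ± 0.35) and Jon65Aiv 21.7-fold lower (log2 -4.44 ± 0.32), while lambdaTry, a trypsin-like protease, was 7.89-fold higher (log2 2.98 ± 0.25).

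Reproductive and chemosensory lists were not past the threshold in females. Of 43 female germline genes, 10 fell, 2 rose and 31 were not past the threshold, with 12 past it when adjusted over the list alone (camera adjusted p = 0.0524). mael was 6.62-fold lower (log2 -2.73 ± 0.19) and vas 10.9-fold lower (log2 -3.45 ± 0.28). Of 37 yolk and eggshell genes, 5 fell, 0 rose and 32 were not past the threshold, with 0 past it when adjusted over the list alone (camera adjusted p = 0.837), and the list's median (0.09) and mean (-0.66) differed in sign. Yp3, a yolk protein, was 30.4-fold lower (log2 -4.92 ± 0.84) and lost its call without female replicate 1 or 2 (log2 -4.86 and -4.99). The spread behind this SE was shared with males, where the list's medians were -3.42 and 0.05 in replicates 1 and 2. The female tests of these genes therefore carry that gap between the male replicates as well. Of 44 accessory gland genes, 1 rose and 1 fell in females, 42 were not past the threshold and 1 was past it when adjusted over the list alone (adjusted p = 0.506). Of 45 testis genes, 4 fell, 1 rose and 40 were not past the threshold, with 2 past it when adjusted over the list alone (adjusted p = 0.937), and mip40 was 36.7-fold lower (log2 -5.20 ± 0.28). Of 48 odorant-binding proteins, 10 fell, 5 rose and 33 were not past the threshold, with 15 past it when adjusted over the list alone (adjusted p = 0.828), among them Obp56d (log2 -3.88 ± 0.16). Of 33 odorant receptors, 1 rose (Or85f, at least 2.42-fold), 0 fell and 32 were not past the threshold, with 0 past it when adjusted over the list alone (adjusted p = 0.294). Or85f lost its call without female replicate 1 or 2 (adjusted p = 0.0691 and 0.174). Of 28 gustatory receptors, 1 rose (Gr43a, a fructose receptor, log2 1.11 ± 0.15), 0 fell and 27 were not past the threshold, with 1 past it when adjusted over the list alone (adjusted p = 0.129). Gr43a lost its call without female replicate 1 or 2 (adjusted p = 0.0716 and 0.147).

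In females, 5864 of 18910 genes (31.0%) differed between the species, 2137 higher and 3727 lower in sechellia, or 63.6% lower, which becomes 36.4% with the sign turned. The share lower was 48.3% with the scanner's processed signals, 49.5% with the series matrix values, 81.1% with median centring, 53.3% with only probes well above background in both species and both sexes, and 82.9% and 76.1% without female replicates 2 and 1. At least 2-fold differences numbered 4507, with 1357 higher and 3150 lower. The 8 highest among genes well above background in both species ran from CG32582 (161-fold, log2 7.33 ± 0.20, adjusted p = 0.00374) through CG15254, v, CG32185, Su(P), AttB, Dbi and CG11911 (33.3-fold, log2 5.06 ± 0.23). v was 63.0-fold higher (log2 5.98 ± 0.16), and AttB, an antibacterial attacin, was 34.8-fold higher (log2 5.12 ± 0.23). The 8 lowest ran from RpL38 (260-fold lower, log2 -8.02 ± 0.56, adjusted p = 0.00390) through CG34335, CG14545, l(1)G0193, mtrm, La, CG3164 and cue (92.0-fold lower, log2 -6.52 ± 0.39). La, an RNA-binding protein, was 103-fold lower (log2 -6.69 ± 0.22). Without female replicate 2, CG34335 (adjusted p = 0.0515), CG14545 (0.104), CG3164 (0.0835) and mtrm (0.125, and 0.0707 without female replicate 1) lost their calls. Melanogaster was well above background and sechellia was not for 1274 genes, and 156 genes showed the reverse. The largest bounds of called genes were at least 38.3-fold (Map205), 8.26-fold (CG10280), 7.89-fold (CG9150) and 5.60-fold (CG31680) higher, and at least 92.7-fold (l(2)35Df), 60.6-fold (CG8928), 57.9-fold (CG7101) and 54.1-fold (SuUR) lower. CG31680 lost its call without female replicate 2 (adjusted p = 0.0617), and CG9150 had 1 array apart from the others (1.71, nearest 3.39). The count of called genes was 2965 without female replicate 1 and 990 without female replicate 2, 9448 with the scanner's processed signals, 8879 with the series matrix values and 10600 with a separate-channel fit.

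**Figure D2:**
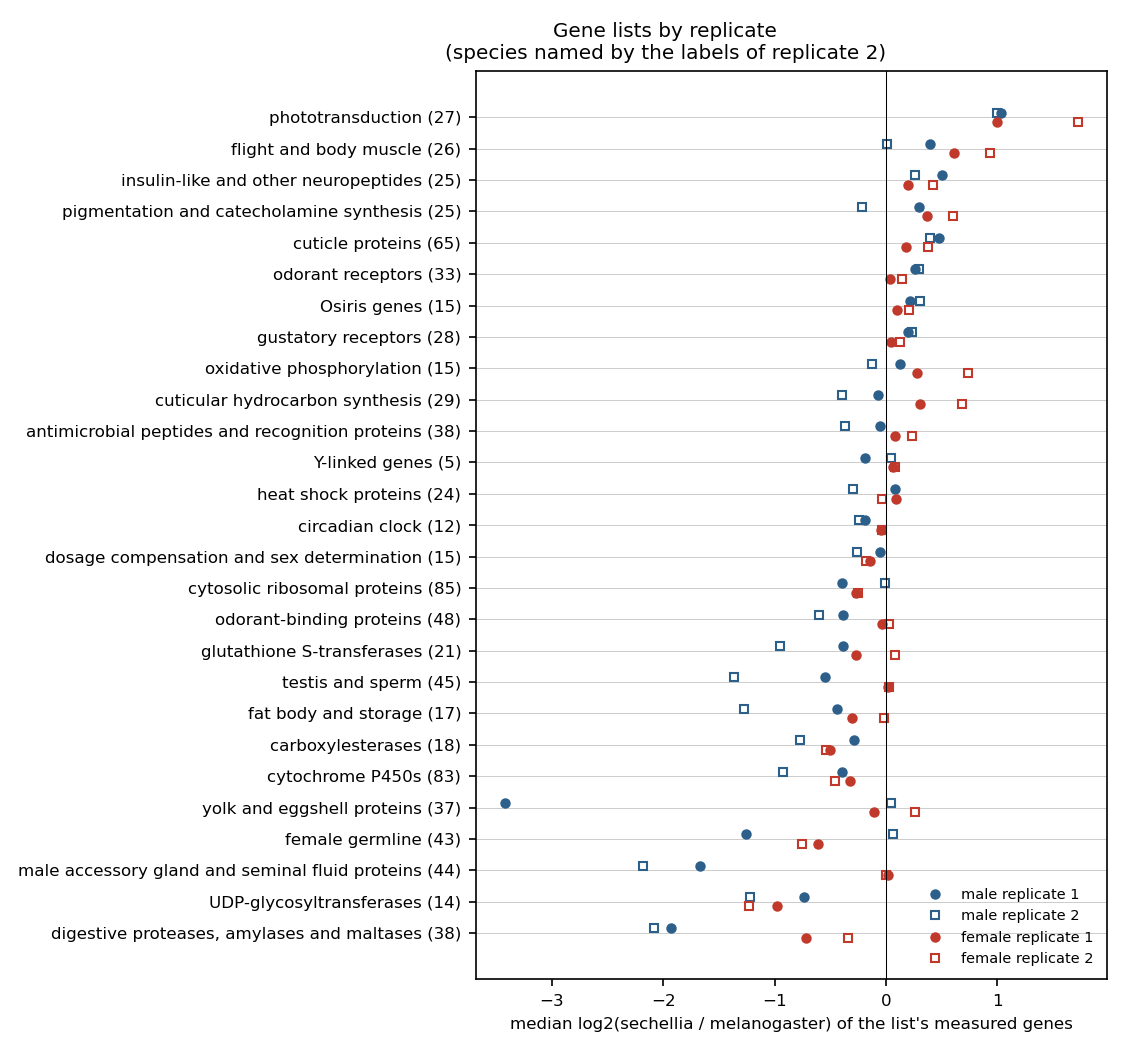
Median log2 ratio of sechellia over melanogaster of each gene list (number of measured genes in brackets), with 1 point per sex and replicate. Phototransduction lay at 0.99 and 1.73 in the 2 female replicates and digestive genes at -1.93 and -2.08 in the 2 male replicates, values that change sign under the labels of replicate 1, and yolk and eggshell genes at -3.42 and 0.05 in the 2 male replicates.

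Averaged over the sexes, single genes called in the same direction in males and in females included v, desat2, Rh5 and the protease Jon65Aiv. v was higher in sechellia by 5.63 ± 0.11 on the log2 scale (SE, n = 4 replicates, adjusted p = 0.00115) and Dbi by 4.85 ± 0.12. desat2 had an average of 3.81 ± 0.13, Rh5 of 3.74 ± 0.18 and Cyp6a18 of 3.81 ± 0.10. RpL38 (log2 -7.65 ± 0.40), CG34335 (log2 -7.66 ± 0.49), Jon65Aiv (log2 -4.73 ± 0.22) and mip40 (log2 -4.55 ± 0.20) were lower. In all, 9806 genes (51.9%) were called, 4012 higher and 5794 lower (59.1% lower, 40.9% with the sign turned), and 5081 of them were at least 2-fold. The share lower was 46.3% with the scanner's processed signals, 48.4% with the series matrix values, 47.1% with only probes well above background in both species and both sexes, and 69.8% with median centring. Without female replicate 1 or 2 the count was 6286 or 4775. Of the genes called in males and in females, 4094 were called in both, 1414 higher in both and 2638 lower in both, against 352 and 901 from independent lists. Another 42 were called in opposite directions, against 1131. Of the 42, 26 were higher in males and lower in females, among them the insulin-like peptide Ilp7 (log2 2.02 ± 0.24 in males and -2.34 ± 0.24 in females, the latter not past the threshold without female replicate 2, adjusted p = 0.0707). Across genes, which are not independent replicates, the male and female differences correlated with Pearson's r = 0.723 and Spearman's rho = 0.716. Male and female samples share the array's probes. The labels name separate RNA of each sex, but female RNA in the melanogaster sample of male replicate 1 stays open. The overlap and these correlations are thus not shown to come from separate RNA. Without each replicate in turn, the genes called in both sexes in the same direction numbered 2310 and 1948 (male replicates 1 and 2) and 2262 and 945 (female replicates 1 and 2), against 4052.

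**Figure D3:**
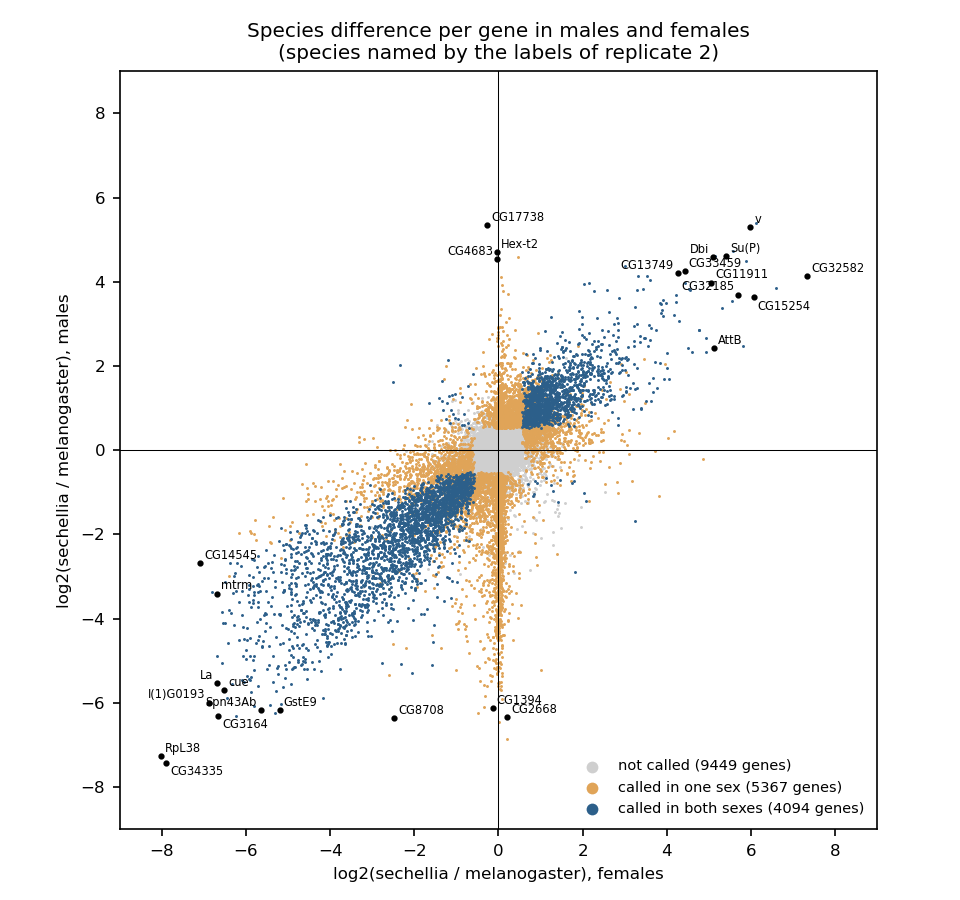
Log2 ratio of sechellia over melanogaster per gene in females (horizontal) and males (vertical), 1 point per gene, with colours for genes called in both sexes, in one or in neither, and black points for named genes. Of the genes called in both, 1414 lay high in both and 2638 low in both, numbers that change places with the sign turned, and 42 lay on opposite sides.

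The sex dependence of the species difference was tested as the male minus the female log2 difference, with digestive, accessory gland, testis and muscle genes among the lists past the threshold. The median difference was -1.43 over the 38 digestive genes (camera adjusted p = 1.78e-09, and adjusted p = 0.970 with an estimated correlation), with 19 past the threshold when adjusted over the list alone. It was -2.13 over the 44 accessory gland genes (adjusted p = 3.50e-08, and adjusted p = 0.970 with an estimated correlation), with 29 past it when adjusted over the list alone, and these genes had a median level of 6.41 in melanogaster females against 14.51 and 14.99 in melanogaster males, so that this difference carries little beyond the male one. It was -0.74 over the 45 testis genes (adjusted p = 1.94e-05, and adjusted p = 0.970 with an estimated correlation), with 20 past it when adjusted over the list alone, and -0.70 over the 26 muscle genes (adjusted p = 1.42e-06, and adjusted p = 0.970 with an estimated correlation), with 0 past it when adjusted over the list alone. The muscle difference was not past the threshold with median centring (adjusted p = 0.766), nor were the accessory gland (0.139) and testis (0.731) differences with only probes well above background in both species and both sexes. The lysozyme LysE stood at -2.90 in males and 1.83 in females, Ilp7 at 2.02 and -2.34, and Acp62F at -4.99 and -0.14, with adjusted p = 0.0808 for the difference of each. Over all genes, limma called 0 at an adjusted p under 0.05, with 4101 at an unadjusted p under 0.05 and 0.0808 the smallest adjusted p. Of 17 other settings, not counting those on the labels, 9 also called 0 and 8 called 527 to 6856 genes, among the latter 1715 with median centring, 1690 without background correction, 2001 with the scanner's processed signals, 1820 with all 8 arrays and a dye term, 749 without male replicate 1 and 6856 with a separate-channel fit. The separate-channel fit counted the 2 dye-exchanged arrays of a replicate as independent, so its count does not measure the spread between replicates. Males and females lay on different slides, so sex and slide cannot be told apart.

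Genes expressed more in males than in females, and the reverse, were compared for how often the species differed. Of 3337 male-biased genes, 1870 (56.0%) were called in males, with 1218 lower and 652 higher in sechellia. In females 24.4% were called, with 197 lower and 617 higher. Of 4510 female-biased genes, 2073 (45.96%) were called in females, with 1805 lower and 268 higher. In males 34.9% were called, with 1195 lower and 379 higher. The median log2 difference of the female-biased genes in males was -0.27. Without male replicate 1, with the classes set anew, that median was -0.013, so the lean to lower values rests largely on this replicate. Of 11063 other genes, 38.4% were called in males and 26.9% in females. The species names change places with the sign turned. Without male replicate 1, 46.9% of male-biased and 23.3% of female-biased genes were called in males, and 20.8% of the others. When only probes well above background in both species and both sexes were kept, 51.1% of male-biased genes were called in males, with the direction turned (370 lower and 487 higher), and 56.1% in females. With the classes set at 4-fold, 9.27% of male-biased genes were called in females. The classes were taken from the sex difference averaged over both species, at an adjusted p under 0.05 (limma) and at least 2-fold. Before the fold bound, that average called 11877 genes, 4405 higher in males and 7472 in females. Within species, 11561 genes differed between the sexes in melanogaster (4434 higher in males, 7127 in females) and 7880 in sechellia (3158 and 4722). Leaving out a female replicate lowered these counts. Sex and slide cannot be told apart in these counts.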

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

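All tests of explanations here were chosen after the result was seen, except that on sequence differences between probes. In the species averages, as in every value here, the labels of replicate 2 set the direction.

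The dye labels of replicates 1 and 2 opposed each other in both sexes. The probes were designed on melanogaster, so those well above background in one species only should more often be the melanogaster ones. With the labels of replicate 2 they were so in 88.2% of cases in males and 89.8% in females, and with the labels of replicate 1 in 11.8% and 10.17%, which argues against a reversal of the labels of replicate 2. An exchange of the red and green columns was argued against by the spike-in controls, whose log ratios had a lowest correlation of 0.916 between any pair of arrays. A candidate explanation that stays open is that the labels of replicate 1 were reversed, and no biological explanation was tested.

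Female-limited transcripts stood high in male replicate 1, most of all in its melanogaster sample. Of 52 yolk, eggshell and germline genes, 100% were raised at least 2-fold there against male replicate 2, and 398 of 433 such genes among all genes were raised. These genes were chosen as at least 16-fold lower in male replicate 2 than in females, which can favour a rise. The 52 reached a median of 30.4% of the female level, with quartiles of 15.6% and 64.9%, so the share differed between genes. Yp1 stood above the female level (17.7, against 16.5 and 16.2 in melanogaster females). An exchange of the whole sample with a female one was argued against by the accessory gland genes, whose median level was 8.10 log2 units above that of melanogaster females. A fault of 1 array was argued against because 100% of the raised genes were lower in sechellia on both arrays of the replicate. Female RNA in that sample may account for its part of the pattern and stays open, while the rise in the sechellia sample of the same replicate (58 of 144 such genes, yolk and eggshell median 9.21 against 6.59 in replicate 2) was not tested.

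More genes were lower than higher in sechellia. Sequence differences from the melanogaster probes may add to this, since outlying probes of genes with at least 3 probes lay on the low side in 63.4% of cases in males and 60.5% in females, the latter only narrowly over the bound of 60% set beforehand. The loess normalization as the cause was argued against by median centring in its place, with which the share lower was 70.2% in males and 81.1% in females. Without background correction the share lower was 59.0% in males and 62.9% in females. Leaving out that step alone thus did not remove the skew. With the scanner's processed signals, which change background correction and normalization together, the share lower was 47.7% in males and 48.3% in females, but lower calls went up too (from 4573 to 5315 and from 3727 to 4566), so that pair of steps stays open, as does a species difference in expression, which was untested. With the sign turned the skew is to higher values in sechellia.

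In 12 of 282 groups of 4 arrays, 1 array lay far from the others (gap over range above Dixon's 95% critical value). With 4 independent values chance gives about 1 in 20. The 4 arrays here are 2 replicates with 2 dye-exchanged arrays each, so that rate does not apply to them. In males these were CG4683 (0.868; 3.64, nearest 4.74), Cyp12d1-d (0.841; 4.38, nearest 3.67), Jon99Fii (0.900; -2.56, nearest -2.33) and TotX (0.8291; -3.62, nearest -2.90). In females they were CG9150 (0.946; 1.71, nearest 3.39), CG10097 (0.876; -2.59, nearest -4.06), Obp56a (0.945; -3.44, nearest -4.55) and Cyp6w1 (0.890; -3.997, nearest -5.41). The others in females were yellow-f2 (0.879; -3.12, nearest -4.60), Prm (0.884; 1.66, nearest 1.53), Lip3 (0.873; -1.10, nearest -2.03) and Crz (0.907; -0.75, nearest -1.94).

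Camera called 14 lists for a male minus female difference, each lower in males, and 0 with an estimated correlation (adjusted p = 0.970). The adjusted p was 1.78e-09 for digestive genes, 3.50e-08 for the accessory gland, 1.42e-06 for muscle and 1.94e-05 for the testis. It was 0.000310 for cuticular hydrocarbon synthesis (median -0.53, 0 genes adjusted over the list alone), 0.00183 for antimicrobial genes (-0.38, 4), 0.00363 for P450 genes (-0.24, 2) and 0.00448 for glutathione S-transferases (-0.48, 4). It was 0.00856 for phototransduction (-0.41, 0), 0.0127 for odorant-binding proteins (-0.40, 10), 0.0312 for yolk and eggshell (-1.45, 0), 0.0328 for oxidative phosphorylation (-0.37, 0), 0.0376 for heat shock (-0.55, 4) and 0.0464 for pigmentation (-0.45, 0). Relative to all genes, the medians of cuticular hydrocarbon synthesis and oxidative phosphorylation changed sign with median centring (0.10 and 0.36). Others came near 0 there: muscle (-0.037, from -0.78), phototransduction (-0.048, from -0.49), heat shock (-0.0020, from -0.63) and pigmentation (-0.13, from -0.53). With only probes well above background in both species and both sexes, the accessory gland (0.139) and testis (0.731) calls were lost, and accessory gland genes had a median level of 6.41 in melanogaster females, so that their difference carries little beyond the male one. Yolk and eggshell genes turned direction without male replicate 1 (adjusted p = 0.0879). Calls were lost without male replicate 2 for P450 genes (0.375), glutathione S-transferases (0.0735), odorant-binding proteins (0.0800), oxidative phosphorylation (0.118) pigmentation (0.3005) and heat shock (0.0504). They were lost without male replicate 1 for phototransduction (0.0886) and oxidative phosphorylation (0.0587), without female replicate 1 for heat shock (0.116), and without female replicate 2 for phototransduction (0.745), yolk and eggshell (0.0585), oxidative phosphorylation (0.330) and pigmentation (0.261). The 13 other lists had adjusted p from 0.117 to 0.921.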

How the results depend on the processing

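Alternatives on the dye labels, direction, overlap and leave-outs of lists were chosen after the data were seen. Of 239 results of named genes past the threshold, 197 kept direction and call in each alternative that keeps every replicate and gave them a value. Some had no value with only probes well above background in both species and both sexes, and this was not counted as a loss. Without some replicate, 94 lost the call. Of 5264 recomputed gene values, 4630 were the same, 249 lost the call, 362 gained it and 23 turned. Of 726 recomputed list results, 596 were the same, 97 lost the call, 28 gained it and 5 turned, and a turn between results that both lacked a call counted as the same. With median centring 9 list results lost the call, 8 gained it and 2 turned. With the scanner's processed signals 4 lost it and 2 gained it. Not all of these are named here. Gene values with the sign turned are not listed, since every sign turns. A share of lower calls counted as the same within 10 percentage points. The median of all genes moved by 0.22 in males and 0.22 in females with the scanner's signals, -0.12 in females and 0.13 for the difference with median centring, 0.16 in males with the strict filter, which also tests fewer genes, and 0.15 in males with the series matrix. Relative to all genes, no list called in males or females changed the sign of its median with the scanner's signals, median centring or the series matrix. The list tests themselves were not run on the series matrix. Probes matching both genomes were not run, as sequences of sechellia were not used here. Signal over background limits the one-species genes to bounds. The separate-channel fit counted the 2 arrays of a replicate as independent, which can raise its counts. Unless said, the cause was not tested.

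The count of called genes in males (7691) was 12947 with a separate-channel fit, and 3372 to 5367 without single replicates. In females (5864) it was 9448 with the scanner's signals, 8879 with the series matrix and 10600 with a separate-channel fit, and 990 to 5420 without single replicates. Averaged (9806), it was 5081 at 2-fold or more, by construction, and 4775 to 9030 without single replicates. The male minus female difference (0) had 1690 without background correction, 2001 with the scanner's signals, 1715 with median centring, 1820 with 8 arrays and a dye term, 527 with only arrays with sechellia in Cy3, 1647 with the matrix, 6856 with a separate-channel fit, and 0 to 749 without single replicates. With the labels as written, limma called 0 in males, 0 in females, 0 averaged and 0 in both sexes in the same direction (17, 0, 4 and 5 at an unadjusted p under 0.05 in males, females, averaged and the difference), since the replicates then cancel.

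The percent of calls lower in sechellia in males (59.5) was 47.7 with the scanner's signals, 70.2 with median centring, 47.4 with the strict filter and 40.5 with the sign turned, and 67.0 to 67.8 without male replicates. In females (63.6) it was 48.3, 81.1, 53.3 and 36.4, with 49.5 for the matrix and 63.6 to 82.9 without single replicates. Genes called in both sexes the same way (4052) were 7249 with the scanner's signals, 6724 with the matrix, 7870 with a separate-channel fit and 945 to 2310 without single replicates. The lists called (29) were 0 with an estimated correlation, 0 with fry and 24 to 32 without single replicates. Genes differing between the sexes were 7021 to 10609 in melanogaster (11561) and 3270 to 6843 in sechellia (7880). The percent of male-biased genes called in females (24.4) was 9.27 at 4-fold and 56.1 with the strict filter. Without male replicate 1 the percentages of male- and female-biased genes called were 46.9 and 23.3 in males and 23.6 and 48.3 in females.

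With the replicate number as a block, 9032 genes were called averaged, 6961 in males, 5564 in females and 0 for the difference (limma, 3858 at an unadjusted p under 0.05). The numbers do not pair the samples (correlation 0.0125), and lists and single named genes were not tested with the block.

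Lists turned as follows: yolk and eggshell without male replicate 1, in males (adjusted p = 0.356, and 2.54e-13 without male replicate 2) and for the difference (0.0879, and 2.89e-18 without male replicate 2); oxidative phosphorylation (0.320) and gustatory receptors (0.0126) for the difference with median centring; and female germline for the difference without male replicate 2 (0.00590, and 1.1e-06 without male replicate 1). Male minus female values turned with median centring to 0.19 (Ggamma30A), 0.068 (ND42), 0.17 (Rh2), 0.23 (TpnC47D) and 0.31 (inaD). In females, ATPsyn-beta turned to 0.32 with the strict filter and 0.37 with the brightest probe, Yp2 to 0.11, alpha-Est7 to 0.11 and cype to 0.97 with both, Est-6 to 0.42 and Hsc70-3 to 0.033 with the brightest probe, Sxl to 0.32 with the scanner's signals and the matrix, and jet to -0.16 with median centring. In males, cype turned to 0.34 with the strict filter and the brightest probe, Sxl ranged from -0.040 without male replicate 2 to 0.55 without male replicate 1, Yp1 from -6.58 without male replicate 2 to 0.89 without male replicate 1, and Yp2 from -3.15 to 0.29 in the same order.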

Other observations

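The test of other sign assignments here was chosen after the result was seen. Insulin-like and other neuropeptides differed both ways. In males 8 of 25 rose, 5 fell and 12 were not past the threshold, with 14 past it when adjusted over the list alone (camera adjusted p = 0.353), and in females 7 rose, 5 fell and 13 were not past it, with 15 adjusted over the list alone (0.280). Ilp3 rose by 1.53 ± 0.16 (log2, SE, n = 2 replicates) in males. Among 38 antimicrobial and recognition genes, 9 rose, 12 fell and 17 were not past the threshold in males (24 adjusted over the list alone, adjusted p = 0.667), and 12 rose, 11 fell and 15 were not past it in females (25 adjusted over the list alone, 0.387). CecA1, a cecropin, was at -3.37 ± 0.26 in males, PGRP-SA, a peptidoglycan sensor, at -3.65 ± 0.34 in males and PGRP-SD at 1.98 ± 0.16 in females. Among 24 heat shock genes, 2 rose, 6 fell and 16 were not past the threshold in males (8 adjusted over the list alone, adjusted p = 0.629), and 4 rose, 4 fell and 16 were not past it in females (8 adjusted over the list alone, 0.586). Hsp22 was at -2.97 ± 0.23 in males and -4.08 ± 0.23 in females, and Hsp70Ba at 1.69 ± 0.16 and 3.93 ± 0.16.

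Among 25 pigmentation genes, 7 rose, 5 fell and 13 were not past the threshold in males (12 adjusted over the list alone, adjusted p = 0.586), and 7 rose, 4 fell and 14 were not past it in females (11 adjusted over the list alone, 0.0599). yellow-c was at 2.59 ± 0.22 in females. Of 18 carboxylesterases, 3 rose, 5 fell and 10 were not past the threshold in males (11 adjusted over the list alone, adjusted p = 0.353), and 2 rose, 4 fell and 12 were not past it in females (10 adjusted over the list alone, 0.614). Est-6 was 12.5-fold lower in males (log2 -3.65 ± 0.35). Of 17 fat body genes, 1 rose, 6 fell and 10 were not past the threshold in males (7 adjusted over the list alone, adjusted p = 0.0809), and 0 rose, 6 fell and 11 were not past it in females (6 adjusted over the list alone, 0.239). Stress gene TotA was at -2.90 ± 0.27 and -3.53 ± 0.27. Of 12 clock genes, 1 rose and 4 fell in males (6 adjusted over the list alone, adjusted p = 0.771) and 0 rose and 3 fell in females (3 adjusted over the list alone, 0.951). The cryptochrome CG3772 was at -2.69 ± 0.29 in males.

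Of 15 Osiris genes, 5 rose and 1 fell in males (6 adjusted over the list alone, adjusted p = 0.0524), with Osi12 at 2.54 ± 0.20, and 0 rose and 1 fell in females (0 adjusted over the list alone, 0.425). Of 15 oxidative phosphorylation genes, 3 rose and 1 fell in males (1 adjusted over the list alone, adjusted p = 0.913) and 2 rose and 2 fell in females (7 adjusted over the list alone, 0.0524). Of 15 dosage compensation and sex determination genes, 1 rose and 6 fell in males (7 adjusted over the list alone, adjusted p = 0.528) and 0 rose and 5 fell in females (5 adjusted over the list alone, 0.348). roX2 was at -1.71 ± 0.23 in males and tra2 at -4.60 ± 0.50 in females. Of 5 Y-linked genes, ARY rose (log2 1.32 ± 0.19) and Pp1-Y2 fell (log2 -1.79 ± 0.38) in males (4 adjusted over the list alone, adjusted p = 0.854), and 0 of 5 were past the threshold in females (0 adjusted over the list alone, 0.412). Pp1-Y2 lost its call without female replicate 1 or 2 (adjusted p = 0.0579). The median, the mean and camera's direction differed in sign for pigmentation, Y-linked, muscle and oxidative phosphorylation genes in males, and for heat shock, Osiris, clock, accessory gland, testis, yolk and glutathione S-transferase genes in females. For the male minus female difference they did so for UDP-glycosyltransferases, cuticle, clock and neuropeptide genes. None of these was past the threshold by camera.

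The 4 replicates allow 8 assignments of the species signs, too few for a share under 0.05. The reading used called 9806 genes and the highest of the others 0, so that 1 of 8 called as many. That reading was chosen because the replicates then correlate, and the labels as written are among the others, so the count tests nothing.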
